A study of Danio rerio with 6 samples.

How the data were processed

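Bulk RNA-seq of whole zebrafish embryos at 22 hours post fertilization was used, with 6 libraries, 3 from synpo2 wild-type and 3 from synpo2 homozygous mutant embryos. The groups and replicate numbers came from the sample titles and genotype labels, and the series design text calls the replicates biological. Per the labels' protocols, embryos were placed in Trizol after euthanasia. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and the GRCz10 genome were used. The authors deposited 1 table of raw counts per library, with whole-number counts for 31484 Ensembl genes, gene coordinates and exonic length in the featureCounts column layout. The counting program, its strand setting, its handling of multiply mapped reads and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Symbols were available for 25752 of the 31484 gene IDs and are printed as the name table gives them, many in human style, with the gene ID where a symbol stands for several genes.

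Library totals ranged from 32714170 to 142789686 counts. Values below 0.1 CPM rest on a few counts in the 5 shallower libraries, so folds of genes nearly absent in mutants are imprecise. Libraries were compared pairwise by a chi-square statistic over genes with at least 20 counts per pair, and no pair agreed within sampling noise.

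Genes were kept with filterByExpr of edgeR 4.0.16 under R 4.3.3, which left 20415. Counts were scaled by TMM, and edgeR's quasi-likelihood F test (robust, two-sided) compared mutant with wild type, with no covariate and Benjamini-Hochberg adjusted p under 0.05. CPM are counts scaled to TMM-adjusted library size over the kept genes (edgeR's cpm), ± is the SD over 3 libraries, and the SE of a log2 fold change is its size divided by the square root of F. Gene lists, 39 in number and chosen before the data were examined, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 where at least 5 members were tested (38 lists), adjusted over all of these. List members were matched by symbol ignoring case, or otherwise by the human-style symbol after dropping a final a or b, a rule set after the names were seen and before any test. Mean log2 CPM per library used a prior count of 2. Genes within 5 Mb of synpo2b were compared with all others by Fisher's exact test.

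The rule for named genes, fixed in advance, took every listed synaptopodin family gene. Its second part took, among genes with adjusted p under 0.05, a mean of at least 1 CPM and ranges apart, the 12 largest rises and 12 largest falls, leaving out genes without a symbol or with a clone-style name. It also took up to 4 members per described list by smallest p, and up to 8 called genes near synpo2b. With fewer than 10 genes passing, the 10 with the smallest p were to take the place of the second part. With 15 called, 11 of them at a mean of at least 1 CPM, this was not used, and 4 genes with a symbol met the second part. Genes named outside the rule are said to be, and some genes are not reported here.

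Alternatives fixed in advance were RLE, upper-quartile and total-count scaling, no filter and a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, non-robust dispersion, the replicate number as a block, each library left out in turn, an estimated inter-gene correlation, fry, list tests without genes within 5 Mb of synpo2b, the gene count without chromosome 1, other windows around synpo2b, and a threshold of 0.01. Thinning wild type replicate 1 to the mean depth of the other libraries was added after the depths were seen. Code was tested on simulated counts for the mutant against wild type comparison, with 200 changed genes among 20144. The 200 were drawn from genes with a mean of at least 1 CPM, so recovery at lower levels was not tested. Members of 1 gene list were moved as well and are not among the 200 or the false calls. edgeR recovered 36% of genes changed by 2-fold, 86% at 4-fold, 96% at 8-fold and 98% at 16-fold, with 12 false calls. DESeq2 recovered 54%, 94%, 98% and 100% with 65 false calls among 20415 genes. In the same simulation, camera called the 1 list that had been moved and 0 others, but the simulated genes were drawn independently, so this does not test correlated lists. A check of GC content was not made, since no genome was used here.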

Results

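RNA from whole zebrafish (Danio rerio) embryos at 22 hours post fertilization was sequenced from 2 genotypes, embryos homozygous for the wild-type synpo2 allele and synpo2 homozygous mutants, with 3 biological replicates of each. synpo2 encodes synaptopodin-2 (myopodin), an actin-binding protein of the muscle Z-disc. The deposited gene counts covered 31484 Ensembl genes in each of the 6 libraries. Wild type replicate 1 held 142789686 counts, 4.26 times the mean of the other 5 libraries. Wild type replicates 2 and 3 held 34822328 and 32850819 counts. Mutant replicates 1 to 3 held 32714170, 32826283 and 34227596. No pair of libraries differed by as little as sampling noise. The first principal component of log2 CPM (counts scaled to library size by edgeR's cpm) took 45.6% of the variance and did not separate the genotypes. Wild type replicate 2 (10.7) lay between mutant replicate 3 (1.28) and mutant replicate 2 (33.2).

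The targeted gene was examined first, as a check of the labels. synpo2b was the synpo2 copy named among the counted genes (ENSDARG00000077157, GRCz10 chromosome 1, 25267662 to 25272368, minus strand, 4 exon entries spanning 3155 nt of counted sequence). Its level was 4.65 ± 1.24 CPM in wild type and 1.60 ± 0.101 CPM in mutants (SD, n = 3 each), a log2 fold change of -1.53 (SE 0.27). The 3 wild-type libraries held 496, 150 and 202 synpo2b counts. The mutant libraries held 57, 52 and 52, and the ranges in CPM did not overlap. The adjusted p by edgeR's quasi-likelihood test was 0.15 over all genes tested and 0.00193 when adjusted over the list alone, that is over the synaptopodin family. DESeq2 gave an adjusted p of 7.96e-05 over all genes. The other family members, which have roles in heart and skeletal muscle, were synpo2la (ENSDARG00000077293, chromosome 13), with a log2 fold change of -1.10 (SE 0.35), and SYNPO2L (ENSDARG00000078696, chromosome 12, matched to synpo2lb), at -0.40 (SE 0.17). Their adjusted p values were 0.349 and 0.443 over all genes, and 0.0246 and 0.0493 when adjusted over the list alone. The labels state neither the lesion nor which synpo2 copy carries it, and a second copy, synpo2a, was not analysed here. Fast skeletal muscle genes were also lower in mutants (median log2 fold change -1.12, lower quartile -1.77). The fall of synpo2b, itself a muscle gene, lay within that range, so it cannot by itself check the labels or show a lesion at synpo2b.

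**Figure D1:**
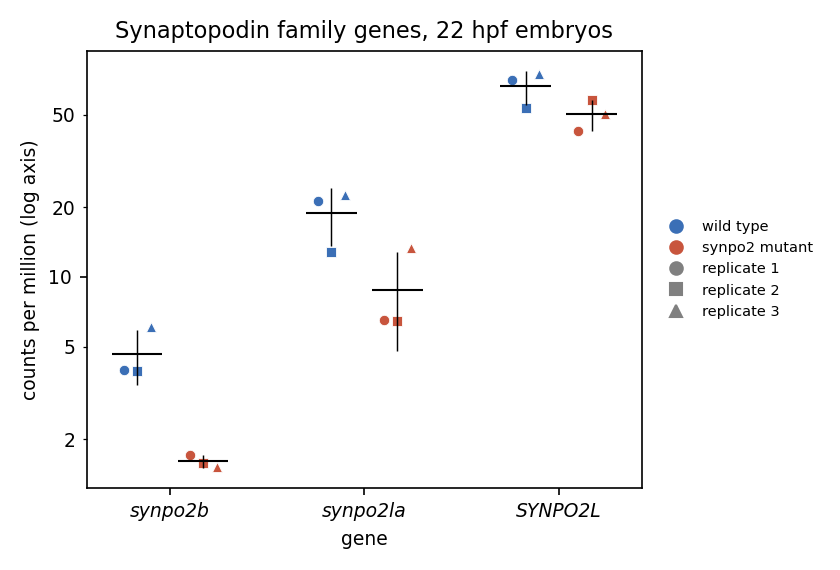
CPM (log axis) of 3 synaptopodin family genes in 3 wild-type (blue) and 3 synpo2 mutant (red) libraries, with symbols for the replicate number and black bars for the mean and SD. The mutant libraries lie between 1.52 and 1.71 CPM for synpo2b, below the 3 wild-type libraries (3.91 to 6.09 CPM).

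Across the transcriptome, 15 of 20415 tested genes changed between the genotypes, 3 higher and 12 lower in mutants (edgeR, adjusted p under 0.05). PER2 (ENSDARG00000034503, chromosome 2), a period gene of the circadian clock whose transcription responds to light in zebrafish, rose from 9.22 ± 1.45 to 26.1 ± 1.67 CPM, by 2.83-fold (SE of the log2 fold change 0.16, adjusted p = 0.0454). asgr1a (ENSDARG00000095963, chromosome 23), named for an asialoglycoprotein receptor, rose from 0.460 ± 0.0987 to 3.05 ± 0.491 CPM, by 2.74 on the log2 scale (SE 0.30, adjusted p = 0.0475). mtdhb (ENSDARG00000004939, chromosome 16), a metadherin gene, fell from 24.1 ± 3.64 CPM to 0.137 ± 0.165 CPM (log2 fold change -7.41, SE 0.67, adjusted p = 0.0301). ccl20a.3 (ENSDARG00000101040, chromosome 2), a chemokine gene, fell from 2.91 ± 0.443 to 0.050 ± 0.0181 CPM (log2 fold change -5.80, SE 0.40, adjusted p = 0.00935).

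Of the 15 genes, 11 were below 0.5 CPM in every mutant library, and 8 had no symbol or a clone-style name. The lowest adjusted p belonged to one of these, si:ch211-69l10.4 (ENSDARG00000098036, chromosome 24), which fell from 8.47 ± 1.62 to 0.0493 ± 0.0330 CPM (adjusted p = 0.00707) and, like the next 3 genes, was named after its values were seen. plxnb2a.2 (a plexin gene, 1.56 CPM in wild type against 0.0299 CPM), znf1177 (a zinc finger gene, 1.13 against 0.119 CPM) and TSHR (the thyrotropin receptor, 0.0461 against 0.747 CPM) changed at mean levels under 1 CPM. Reads shared with near-identical copies are a limit for the clone-named, zinc finger and tandem-copy genes, since the handling of multiply mapped reads is not given in the sources used here. The count of 15 was 463 with DESeq2 (147 higher and 316 lower, with the 15 among them), 44 with no filter on low counts and 8 with a stricter filter. It was 2 without wild type replicate 3, 2 without mutant replicate 1, 0 without mutant replicate 2 and 8 without mutant replicate 3. asgr1a, TSHR and znf1177 lost their calls without any 1 of the 6 libraries (adjusted p for asgr1a 0.0692 to 0.315, TSHR 0.0809 to 0.315, znf1177 0.073 to 0.341). PER2 was not called without wild type replicate 1 (0.0599), wild type replicate 3 (0.178) or mutant replicates 1 (0.179), 2 (0.33) and 3 (0.142). mtdhb was not called without wild type replicates 1 (0.0809), 2 (0.0757) and 3 (0.128) or mutant replicate 2 (0.273). ccl20a.3 was not called without wild type replicate 3 (0.0547) or mutant replicates 1 (0.0781) and 2 (0.163). plxnb2a.2 was not called without wild type replicate 3 (0.0685) or mutant replicates 1 (0.179), 2 (0.273) and 3 (0.14), and si:ch211-69l10.4 without mutant replicate 2 (0.0775). At an unadjusted p under 0.05, 2292 genes (11.2%) passed, and the ranges of the genotypes were apart for 18.1% of genes. Chance gives 10% as an average over splits of the libraries, but a single split can lie far from it, since genes vary together. Over the other splits into 3 and 3, the count at an unadjusted p under 0.05 ran from 93 to 2749.

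Genes of the circadian clock moved in both directions. Of 35 tested members of this list, 6 rose and 2 fell when adjusted over the list alone, and 27 did not pass. By edgeR 1 of the 35 (PER2) passed over all genes. tefa, a PAR bZIP transcription factor gene, was at 62.0 ± 2.60 CPM in wild type and 106.8 ± 3.19 CPM in mutants (log2 fold change 0.78), and CRY1 (ENSDARG00000045768), a cryptochrome gene, was at 14.9 ± 2.48 and 37.7 ± 2.79 CPM (log2 fold change 1.35). Both had an adjusted p of 0.000624 by edgeR over the list alone, against 0.0531 and 0.0546 over all genes. DESeq2 gave adjusted p values of 2.12e-07 for tefa and 1.34e-08 for CRY1 over all genes. Another cryptochrome gene, cry3a, fell from 125.0 ± 1.76 to 84.9 ± 9.44 CPM when adjusted over the list alone (adjusted p = 0.0105). As a set the list was not called (camera, adjusted p = 0.101), but it was called higher with the stricter filter (adjusted p = 0.0367) and without wild type replicate 3 (adjusted p = 0.048). It was at an adjusted p = 0.802 with an estimated correlation and at 0.491 by fry.

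**Figure D2:**
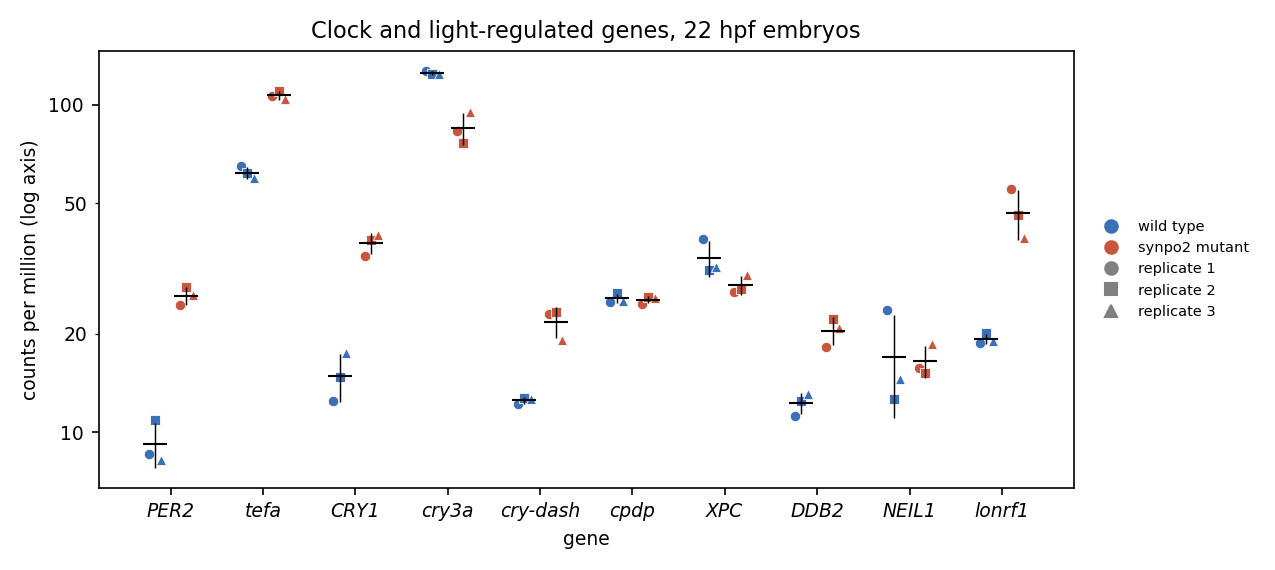
CPM (log axis) of 4 clock genes, of 5 light-regulated repair and photolyase genes and of lonrf1 in each library, with mean and SD as black bars, wild type in blue and synpo2 mutants in red. PER2, tefa, CRY1, cry-dash, DDB2 and lonrf1 are higher in the 3 mutant libraries than in the 3 wild-type libraries, cry3a and XPC are lower in them, and cpdp has means of 25.6 and 25.4 CPM (lonrf1 was chosen after its values were seen).

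Of 38 gene lists with at least 5 tested members, 15 were called by camera with a preset correlation of 0.01, 3 higher and 12 lower in mutants. With an estimated correlation the call was kept for 0 of the 15 (lowest adjusted p = 0.739 with an estimated correlation), where 1 list was under an unadjusted p of 0.05. The fry test called 0 lists (lowest adjusted p = 0.0954), with 4 under an unadjusted p of 0.05.

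Genes of the fast skeletal muscle sarcomere were lower in mutants, with 27 of 27 members below wild type and a median log2 fold change of -1.12. When adjusted over the list alone, 24 fell and 3 did not pass, and over all genes 0 passed (camera adjusted p = 4.75e-27, adjusted p = 0.739 with an estimated correlation). The muscle enolase ENO3 was at 139.9 ± 27.3 CPM in wild type and 82.3 ± 9.22 CPM in mutants. CASQ1 (ENSDARG00000038716), a calsequestrin gene of the sarcoplasmic reticulum, was at 14.2 ± 4.74 and 4.69 ± 1.63 CPM, and the fast myosin heavy chain genes myhz2 and myhz1.2 had log2 fold changes of -1.83 (SE 0.43) and -1.71 (SE 0.41). Mean log2 CPM of the list was 7.70, 6.81 and 7.66 in wild type replicates 1 to 3, and 5.69, 5.54 and 6.62 in mutant replicates 1 to 3. Mutant replicate 3 lay close to wild type replicate 2.

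The slow skeletal muscle sarcomere list was also lower (15 of 18 members, median -0.30, camera adjusted p = 0.00193, adjusted p = 0.739 with an estimated correlation). Its leading members were STAC3, a component of the excitation-contraction machinery, with a log2 fold change of -0.89, the troponin gene tnni1d (-1.49), MYBPC3 (-0.68) and the slow myosin gene smyhc1 (-0.48), and 0 of 18 passed over the list alone. The list of Z-disc proteins and synaptopodin-2 partners was lower for 27 of 37 members (median -0.24, camera adjusted p = 0.00249, adjusted p = 0.739 with an estimated correlation). The members actn3a (-0.95), myoz1b (-1.58), ldb3b (-1.13) and XIRP2 (ENSDARG00000071113, -0.57) led, and 0 passed over the list alone. Smooth muscle genes were lower for 7 of 9 members (median -0.16, mean -0.48, camera adjusted p = 0.0295, adjusted p = 0.739 with an estimated correlation), and 8 did not pass over the list alone. Among them acta2, smooth muscle actin, fell from 1.92 ± 0.171 to 0.437 ± 0.120 CPM when adjusted over the list alone (adjusted p = 0.00234), and it was at an adjusted p of 0.0933 over all genes. DES (ENSDARG00000058656) was at -0.72 on the log2 scale, and the remaining members had an unadjusted edgeR p of 0.427 or more. In the cardiac muscle list, which was not called (adjusted p = 0.522), myh7ba fell from 6.22 ± 0.969 to 1.97 ± 0.327 CPM when adjusted over the list alone.

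**Figure D3:**
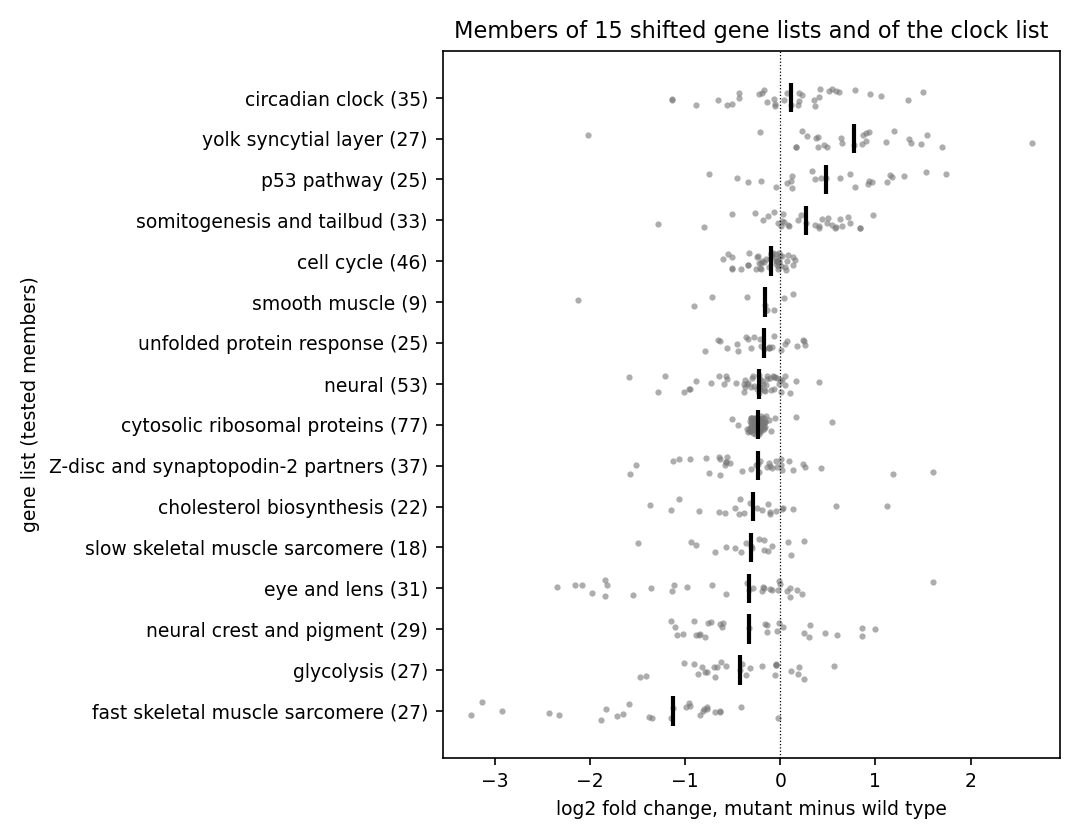
Log2 fold change (mutant minus wild type) of each tested member of the 15 called gene lists and of the circadian clock list, 1 grey point per gene, with a black bar at the median of the list and the number of members in brackets. The fast muscle list has the lowest median, -1.12, and the yolk syncytial layer list the highest, 0.78.

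Genes of eye and lens were lower for 25 of 31 members (median -0.33, mean -0.68, camera adjusted p = 5.17e-05, adjusted p = 0.739 with an estimated correlation). The members with the smallest p were lens genes, the water channel MIP (ENSDARG00000037285) at -2.16 and the crystallins cryba1b (-2.34), CRYBB1 (-1.84) and crybb1l2 (-1.97), and 0 members passed over the list alone. Mean log2 CPM of the list was 2.79, 2.22 and 2.47 in wild type replicates 1 to 3, and 1.44, 1.44 and 2.31 in mutant replicates 1 to 3. Mutant replicate 3 lay within the wild-type range. Neural genes were lower for 45 of 53 members (median -0.22, camera adjusted p = 0.000151, adjusted p = 0.834 with an estimated correlation). They were led by the Notch target her4.1 (-1.28), GAD1 (ENSDARG00000027419, -1.01), FABP7 (ENSDARG00000034650, -1.59) and the neurofilament gene nefma (-0.89), and 0 passed over the list alone. The CPM ranges of FABP7 and nefma overlapped between the genotypes. By library, the mean log2 CPM of the neural list was 4.86, 4.47 and 4.64 in wild type replicates 1 to 3. It was 4.06, 4.25 and 4.71 in mutant replicates 1 to 3, with mutant replicate 3 within the wild-type range. The camera call of the neural list was lost without mutant replicate 1 (adjusted p = 0.0954). Neural crest and pigment genes were lower for 20 of 29 members (median -0.33, camera adjusted p = 0.00405, adjusted p = 0.739 with an estimated correlation). The pteridine gene gch2 was at 101.7 ± 9.84 CPM in wild type and 50.1 ± 16.7 CPM in mutants and the melanosome gene pmela at 28.4 ± 2.85 and 18.6 ± 2.99 CPM, while the neural crest marker crestin was at 12.3 ± 2.37 and 22.2 ± 4.12 CPM. Of the 29 neural crest and pigment genes, 0 passed over the list alone.

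**Figure D4:**
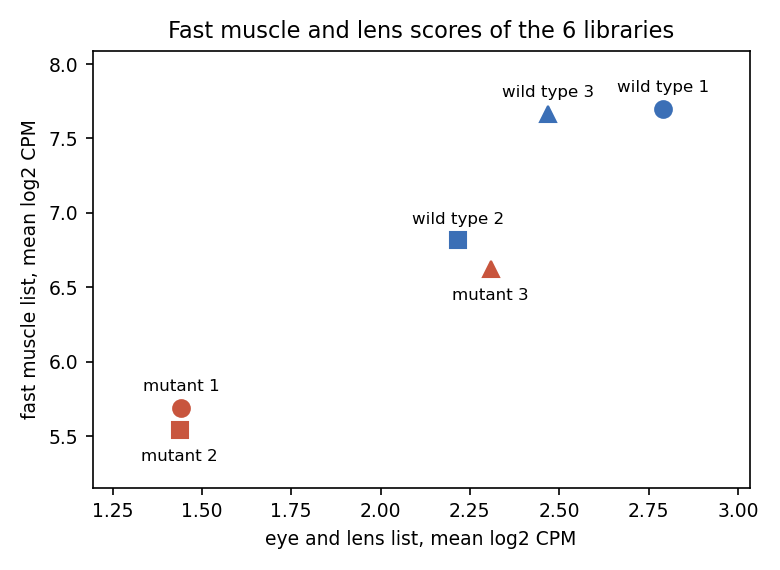
Mean log2 CPM of the fast skeletal muscle list (vertical axis) against that of the eye and lens list (horizontal axis) in the 6 libraries, wild type in blue and synpo2 mutants in red, 1 point per library. Mutant replicate 3 (2.31 and 6.62) lies next to wild type replicate 2 (2.22 and 6.81), and mutant replicates 1 and 2 lie lowest on both axes.

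Genes of somitogenesis and the tailbud were higher in mutants (median 0.27, camera adjusted p = 0.00533, adjusted p = 0.802 with an estimated correlation). The caudal homeobox gene cdx4 was at 0.73, the presomitic mesoderm genes msgn1 and tbx16 at 0.84 and 0.71, and the segmentation clock gene her1 at 0.54 on the log2 scale. Of the 33 members, 0 passed over the list alone. The call was lost without wild type replicate 2 (adjusted p = 0.0959) and without mutant replicate 2 (adjusted p = 0.0987). Yolk syncytial layer genes had a median of 0.78 (camera adjusted p = 0.0454, adjusted p = 0.901 with an estimated correlation). MTTP, which loads lipid onto apolipoprotein B, was at 1.48, DGAT2 at 2.64, the apolipoprotein gene apobb.1 at 1.55 and apoea at -2.02, and 0 members passed over the list alone. Mean log2 CPM of this list was 8.19 in mutant replicate 1 and 5.34 in mutant replicate 3, on either side of the wild-type values (5.90 to 7.03). Without mutant replicate 1 its median was -0.12 and it was called lower (adjusted p = 0.00625). It was not called without wild type replicate 1 (adjusted p = 0.198) or without wild type replicate 3 (adjusted p = 0.391).

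Genes of the p53 pathway were higher in mutants (median 0.48, camera adjusted p = 1.03e-05, adjusted p = 0.739 with an estimated correlation). Of 25 members, 6 rose and 1 fell when adjusted over the list alone, and 18 did not pass. The DNA damage recognition gene DDB2 rose from 12.3 ± 0.929 to 20.4 ± 1.99 CPM, the initiator caspase gene casp8 from 7.60 ± 1.80 to 22.0 ± 9.56 CPM and PHLDA3 from 10.4 ± 3.55 to 25.7 ± 8.76 CPM, while PLK2 (ENSDARG00000090752) fell from 8.92 ± 1.3 to 5.31 ± 0.376 CPM. Mean log2 CPM of the list was 4.37, 4.19 and 3.98 in wild type and 5.07, 4.63 and 4.41 in mutants, in the order of the replicate numbers.

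Glycolysis genes were lower for 22 of 27 members (median -0.43, camera adjusted p = 9.81e-05, adjusted p = 0.739 with an estimated correlation). The leading members were ENO3, which is also in the fast muscle list, at -0.77, ENO1 (ENSDARG00000022456) at -0.90 and PKM (ENSDARG00000099860) at -1.41, with GPI (ENSDARG00000103826) at 0.56. Genes of the unfolded protein response were lower (18 of 25 members, median -0.17, camera adjusted p = 0.00844, adjusted p = 0.802 with an estimated correlation). The endoplasmic reticulum chaperone genes PDIA4, HSP90B1 and HSPA5 fell by 0.56, 0.65 and 0.46 on the log2 scale when adjusted over the list alone. Cholesterol biosynthesis genes were lower for 17 of 22 members (median -0.28, camera adjusted p = 0.00649, adjusted p = 0.802 with an estimated correlation). The regulator srebf2 was at -0.42 and NSDHL, an enzyme of the pathway, at -0.85. Cell cycle genes were lower for 37 of 46 members by a median of -0.09 (camera adjusted p = 0.0124, adjusted p = 0.802 with an estimated correlation). The replication licensing gene CDC6 was at -0.51 and the cyclin E genes CCNE2 and CCNE1 at -0.50 and -0.54. Cytosolic ribosomal protein genes were lower for 75 of 77 members (median -0.24, camera adjusted p = 0.00365, adjusted p = 0.901 with an estimated correlation), and their median was 0.071 without wild type replicate 1. In the glycolysis, cholesterol biosynthesis, cell cycle and ribosomal protein lists, 0 members passed over the list alone. Single left-out libraries also ended several calls. The unfolded protein response was not called in 3 cases (wild type replicates 1 and 2 and mutant replicate 3, adjusted p = 0.181, 0.0957 and 0.105), nor cholesterol biosynthesis in 4 (wild type replicates 1 and 2 and mutant replicates 2 and 3, adjusted p = 0.0943, 0.0957, 0.0671 and 0.0651). The cell cycle list was not called in 2 (wild type replicate 2 and mutant replicate 1, adjusted p = 0.0959 and 0.266), nor ribosomal proteins in 2 (wild type replicate 1 and mutant replicate 1, adjusted p = 0.0621 and 0.152), nor smooth muscle in 1 (wild type replicate 2, adjusted p = 0.0957).

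Apart from the Z-disc list, 4 lists that bear on actin functions of synaptopodin-2 were not called by camera. These were actin filament assembly and focal adhesion (adjusted p = 0.860), SRF and MRTF targets (0.494), Hippo-YAP targets (0.229) and chaperone-assisted autophagy (0.703). Within the first, the parvin gene PARVA (ENSDARG00000035629) fell from 4.49 ± 0.826 to 1.88 ± 0.227 CPM and the fascin gene FSCN1 (ENSDARG00000037747) from 0.661 ± 0.144 to 0.18 ± 0.0325 CPM when adjusted over the list alone. In the heat shock list (0.435), the collagen chaperone gene SERPINH1 (ENSDARG00000075954) rose from 189.1 ± 16.3 to 286.1 ± 27 CPM when adjusted over the list alone. The other SERPINH1 gene (ENSDARG00000019949) was at 163.2 ± 70 and 93.0 ± 9.1 CPM, and hsp70.3 and HSP90AA1 had log2 fold changes of -1.33 and -0.72, none of which passed. Myogenic regulators (0.101), nonsense-mediated decay factors (0.486), interferon-stimulated genes (0.643) and nuclear-encoded oxidative phosphorylation (0.590) were not called either. The same held for mitochondrially encoded genes (0.109), extracellular matrix and tendon (0.116), hypoxia (0.229), erythroid (0.311), endoderm and gut (0.409), periderm and epidermis (0.455), pronephros and podocyte (0.486), vascular endothelium (0.621), myeloid cells (0.638), hatching gland (0.703), retinoic acid and Hox genes (0.703) and notochord (0.841), each value being camera's adjusted p. The direction from camera differed in sign from the list median for the periderm, interferon, cardiac, and retinoic acid and Hox lists, and median and mean differed in sign for the periderm, interferon, retinoic acid and Hox, actin and oxidative phosphorylation lists. Camera's direction differed in sign from the mean for the cardiac, actin and oxidative phosphorylation lists.

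Homozygous mutants chosen by genotype share the haplotype around the mutated gene, so genes near synpo2b were counted apart, which bears on that haplotype only if synpo2b is the mutated copy. Of 139 tested genes within 5 Mb of synpo2b on chromosome 1, 0 were called by edgeR, against 15 of 20275 elsewhere (Fisher's exact test, two-sided, p = 1). With so few calls in all, 0 among 139 was likely with or without an effect of the haplotype, so this test could hardly decide. At an unadjusted p under 0.05, 9 of the 139 passed (6.47%), and DESeq2 called 1 of them (exact p = 0.378). The median size of the log2 fold change was 0.15 within the window and 0.22 outside it.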

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

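Thinning wild type replicate 1 was chosen after the depths were seen, and the other alternatives were fixed before the data were examined. The count of 15 changed genes was 17 with RLE and with upper-quartile scaling (5 higher, 12 lower each), 10 with library totals, 17 with limma-voom (12 shared), 15 with non-robust dispersion, 14 with the thinned library (13 shared), and 15 without genes on chromosome 1. It was 463 with DESeq2, 44 with no filter (the 15 among them), 8 with a stricter filter and 3 at an adjusted p under 0.01. Leaving out 1 library gave 0 to 16 genes, with 2 without wild type replicate 3, 2 without mutant replicate 1, 0 without mutant replicate 2 and 8 without mutant replicate 3. The cause was not tested, and each of these fits also had fewer samples. PER2 and asgr1a lost their calls with library totals (adjusted p = 0.0991 and 0.0698) and with the stricter filter (0.05002 each), and asgr1a with the thinned library (0.0527).

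The synpo2b log2 fold change was -1.52 with DESeq2, where it passed (adjusted p = 7.96e-05). Its adjusted p was 0.111 to 0.686 in the other alternatives, with -1.64 to -1.29 over the left-out libraries. The number of called lists was 0 with an estimated correlation and 0 with fry, and 14 or 15 with other scalings and filters. It ranged from 11 to 16 over the left-out libraries. Over the left-out libraries the median of ribosomal proteins ranged from -0.43 to 0.071 (the highest without wild type replicate 1, adjusted p = 0.0621) and that of the yolk syncytial layer list from -0.12 (without mutant replicate 1, adjusted p = 0.00625) to 1.25. The cause was not tested. The yolk syncytial layer list was also not called with library totals (adjusted p = 0.071), no filter (0.109), the stricter filter (0.0554), the replicate number as a block (0.082, median 0.38) or without genes within 5 Mb of synpo2b (0.0645). Within 5 Mb of synpo2b, 0 genes were called in each edgeR and limma-voom alternative, left-out libraries included (0 to 0), and 1 with DESeq2. With the replicate number as a block, 0 genes and 14 lists were called and synpo2b was at -1.50 (adjusted p = 0.385). Deviations of same-numbered libraries correlated at -0.23, -0.10 and 0.18, so the numbers were not taken to pair samples. Values below 0.1 CPM rest on few counts. Scalings left the median log2 fold change of all genes at 0.026 or less.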

Other observations

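The tests of linkage and of wild type replicate 1 left out, the definitions of genes present in 1 genotype, and the choice of genes in the next paragraph were made after results were seen. The other tests were written down before their values were seen.

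At an adjusted p under 0.1 by edgeR there were 58 genes, the 15 called ones among them. The genes below lay between the thresholds with ranges apart and were picked after their values were seen. FST (ENSDARG00000052846), the activin and myostatin antagonist follistatin, was at 59.8 ± 4.51 CPM in wild type and 147.8 ± 28.0 CPM in mutants (adjusted p = 0.0549). HSPA12B, an endothelial HSP70-family gene, was at 3.44 ± 0.824 and 25.6 ± 10.1 CPM (adjusted p = 0.0582). TXNIP (ENSDARG00000070000), a thioredoxin inhibitor that responds to glucose, was at 6.05 ± 0.382 and 1.82 ± 0.141 CPM (adjusted p = 0.0546). FITM1, a lipid droplet gene of skeletal muscle, was at 39.2 ± 9.75 and 12.5 ± 2.75 CPM (adjusted p = 0.0920).

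Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 15 changed genes (the real one), and the highest of the others gave 0. For called gene lists, 5 of the 10 gave at least 15, the real one included, and the highest other gave 18. The 10 splits are too few for a share under 0.05. The 18 lists came both from wild type replicates 1 and 3 with mutant replicate 3 against the rest, and from wild type replicate 1 with mutant replicates 1 and 2 against the rest. The first of these splits had 2749 genes at an unadjusted p under 0.05, against 2292 for the genotypes, so the libraries also differ in a way that crosses genotype.

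Fast muscle and lens genes were lower and tailbud genes higher in mutants. For the fast muscle list, the depth of wild type replicate 1 is argued against as the cause, since its median log2 fold change was -1.04 without that library. That test did not cover the lens and tailbud lists. A candidate explanation of the whole pattern is that mutant libraries came from younger embryos. The fast muscle score difference was -1.44 (95% interval -2.68 to -0.20) and became -0.49 (-1.41 to 0.43) with the lens score as covariate, which met what had been written for a younger stage, but any cause that lowers both lists would shrink the difference too, and tailbud, higher by 0.23, had a 95% interval of -0.061 to 0.53. A younger stage therefore cannot be told apart from an effect of genotype on the pace of development or on muscle and lens together, which was not tested.

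Some genes were present in 1 genotype and nearly absent in the other: by a first definition, at least 1 CPM in each library of a genotype and at most 0.1 CPM in each of the other, there were 9 genes, all in wild type only and all among the 15 called (highest other split, 1). A looser definition, tried after the first had been counted, gave 20 (at least 0.5 CPM and 10-fold), 16 in wild type only and 4 in mutants only. Of these 20 genes, 1 lay on chromosome 1 (mfap4.7, in mutants only). Of the 9 genes 0% lay on chromosome 1 and 1 gene lay on an unplaced scaffold, while the others lay on other chromosomes. For the genes placed elsewhere this argues against linkage to synpo2b, but it says nothing of synpo2a, should that copy be the mutated one. The exact upper 95% limit of the share on chromosome 1 was 33.6%, or 48.2% with the scaffold gene counted there. That limit adds little, since the 9 genes are the whole set by the definition and not a sample. Their lowest level in wild type replicates 2 and 3, whose depths are like those of the mutants, was 1.1 CPM and their highest level in mutants 0.0874 CPM, as the definition largely requires. Different genetic backgrounds of the genotypes may be a source, but the test of pairs within 200 kb decided nothing. Under both definitions the 0 pairs seen equal the random median of 0, so the bound written beforehand could not be missed by a low value. The first definition leaves out some changed neighbours, picked here after their values were seen, and of these the looser one takes in ENSDARG00000071648 alone. On chromosome 4, ENSDARG00000101756 (68816117 to 68823793, log2 fold change -4.43) lies beside the called ENSDARG00000105279 (from 68824615, -7.94). On chromosome 22, the spans of ENSDARG00000071648 (-5.83) and ENSDARG00000071651 (-4.82) overlap on opposite strands. Reads may be shared between them, since the strand setting is not given, but an overlap of their exons was not checked. Such neighbours were not tested against random sets.

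Clock genes moved in both directions (6 rose and 2 fell when adjusted over the list alone, and the list was not called), and the pattern weighed here, higher PER2, tefa, CRY1, cry5 and lonrf1, was picked after these values were seen. By edgeR PER2 alone of them was called over all genes, while DESeq2 also called tefa, CRY1 and lonrf1. Light or time of day at collection could be a cause, and 5 light-regulated genes were tested that had been chosen before their own values were seen, though DDB2 belongs to the p53 list, already seen to be higher. Their median log2 fold change was -0.014, under the bound of 0.1 written beforehand as evidence against it, yet cry-dash (0.80) and DDB2 (0.74) were higher with ranges apart while XPC was at -0.28. The other condition written for light as the cause, fry (limma's rotation test) passing 0.05 over the set, was met, while the condition of a median over 0.3 was not. The bound on the median was judged wrong after the value was seen, because a median over genes that go both ways decides nothing, so light or time of day and genotype cannot be told apart here.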
